A study of Mus musculus with 2 samples.

How the data were processed

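The data were 2 lists of 6mA MeDIP-seq peaks from mouse embryonic brain, 1 list for the E8.5 library and 1 for the E9.5 library, placed in their groups by the sample titles. Per the labels' protocols, genomic DNA was sonicated to 100 to 300 bp, ligated to adapters and immunoprecipitated with a commercial 6mA kit, and about 10% was kept aside as input before the pull-down. The libraries were amplified by PCR and sequenced on an Illumina NovaSeq. The protocols also describe a low-folate stem cell line and embryos from mothers given a folate antagonist, and no sample of either was analysed here.

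Trimming with cutadapt 1.9.2, alignment with Bowtie2 2.2.4 and the genome build mm10 are given per the submitters' processing notes, and the file headers name aligned files from which duplicates had been removed. Peaks were called by the authors per library with MACS 2.1.1.20160309 in paired-end mode, per the file headers, at a p-value of 0.01 with an effective genome size of 1.27e+09, local backgrounds over 1000 and 10000 bp and at most 2 duplicates kept per position. The headers name the same input library as the control of both lists, and the stage of that input is not given in the sources used here. Per the file headers, 16538763 E8.5 and 16657092 E9.5 fragments were read, of which 15375941 and 15349825 were kept, with mean fragment sizes of 256 and 271 bp, and 9603633 of 10670523 input fragments were kept. The pileup column of the deposited files is a signal, the coverage by fragments at the summit. The fold enrichment deposited by the authors is a ratio of the pileup to the local background, each with a pseudocount of 1. The p-value and q-value columns deposited by the authors hold −log10 values. A threshold on p of 0.01 without correction admits many chance peaks. The lowest background recovered from the deposited pileups and folds was 3.05 fragments at E8.5 and 3.14 at E9.5, against a mean coverage of 1.46 and 1.54 over the chromosome spans. No antibody control other than the input was used here, so enrichment by the antibody for reasons other than 6mA was not measured.

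All 1006 E8.5 and 1239 E9.5 peaks lay on the numbered chromosomes, X or Y, and all were used. The gene table used was RefSeq on GRCm38.p6, the assembly called mm10, with 49939 placed genes, of which 21883 were protein-coding and 12727 long non-coding. It gives gene bodies without strand, exons or sequence. The design fixed before the data were examined asked for promoters, exons and introns, for the highest promoter peaks, and for the repeat and base content of peaks. None of these could be had from gene bodies, so peaks were instead put, by summit, within 1 kb of either gene end, inside a gene body or outside genes, and base content was not analysed here. Chromosome lengths were replaced by the span from the first to the last gene or peak.

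Overlap was counted with bedtools 2.31.1 at a minimum of 1 bp. Shares carry exact Clopper-Pearson intervals and pileups exact Poisson intervals. PCR copies are not independent molecules, so these intervals cover counting error only. Chance was described by 1000 random placements that kept each peak's length and chromosome, and in an added version its 1 Mb window. The background of a peak was recovered from its pileup and fold, and a background within 0.005 of the library's lowest value was called the genome-wide minimum. Shared and other peaks of a library were compared by two-sided permutation tests of medians with 100000 resamples, and Benjamini-Hochberg adjustment covered the 6 tests. A gene was counted where a peak overlapped its body extended by 2 kb, and the count of each list was set beside 10000 random lists of protein-coding genes matched on 20 bins of gene length but not on position. With 1 library per stage no test between the stages was possible.

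The groups, tests, 15 gene lists, 5 gene families, alternatives and the rule for named regions were chosen before the data were examined. That rule named, for each library, the 8 peaks without a partner with the highest fold, the 8 shared pairs with the highest mean percentile rank of fold, and the members of each list with a peak, up to 6 by fold. The peak-rich windows, the subsets by q of 0.05 and by background, the counts by gene length, and the region map were chosen after the data were examined, as were the genes named only as neighbours of those windows. Alternatives covered a stricter q, the upper 50% of folds, chromosome Y, the 1% of peaks with the highest pileup, other definitions of overlap, other extensions of genes and unmatched random lists. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

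The steps were tested on simulated data. In 20 simulations of 1006 E8.5 peaks placed at random with 200 planted overlaps, 100% of the planted overlaps were found, with a mean of 0.6 further overlaps by chance. Of 100 random gene lists, 2 fell in the top 5% of matched lists, and no matched list reached a list with 20 planted members. Shuffled folds gave a p under 0.05 in 2 of 100 sets, and a planted shift of 0.3 in fold gave a permutation p of 0.0005.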

Results

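DNA N6-methyladenine (6mA), adenine carrying a methyl group on its amino nitrogen, was mapped in mouse embryonic brain by MeDIP-seq, in which an antibody against the modified base pulls down sonicated genomic DNA that is then sequenced. The series concerns 6mA and H3K9me3-marked heterochromatin during neural tube development, and its design asks where in the genome 6mA lies. There were 2 libraries, 1 from brain at embryonic day 8.5 (E8.5) and 1 from brain at embryonic day 9.5 (E9.5), both labelled as receiving no treatment. The stage of each library was known from the labels alone, since the library names inside the peak files carry no stage. Those names share a stem and differ in a number, as names of samples of the same group would, so the stages could not be checked against the files. Embryos with neural tube defects, which the design text also describes, were not analysed here. The E8.5 library held 15375941 fragments after duplicate filtering and the E9.5 library 15349825, and both were set against the same input library of 9603633 fragments. With 1 library per stage there were no replicates, so no difference between the stages was tested, and all intervals below are exact 95% intervals that cover counting error only.

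Few peaks reached a corrected threshold at either stage. The authors' list held 1006 peaks at E8.5 and 1239 at E9.5, which covered 409784 and 529268 bp. The median fold enrichment over background, the authors' own value for each peak, was 2.62 at E8.5 (quartiles 2.33 and 2.96) and 2.65 at E9.5 (quartiles 2.38 and 2.90), and the highest values were 6.66 and 7.49. The median peak rested on a pileup of 11 overlapping fragments in each library. For 466 E8.5 peaks (46.3%) and 604 E9.5 peaks (48.7%) the background was the genome-wide minimum of 3.05 and 3.14 fragments, not the local input. That minimum lay above the mean coverage of 1.46 and 1.54. A low fold or a high q there need not mean weak enrichment over the local input. A q-value of at most 0.05 was reached by 129 E8.5 peaks (12.8%, interval 10.8% to 15.0%) and by 159 E9.5 peaks (12.8%, 11.0% to 14.8%), while 755 and 917 peaks had a q of 1. At a q of at most 0.001, 76 and 90 peaks were left.

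The E8.5 and E9.5 libraries were compared to find which regions were enriched at both stages. Of the E8.5 peaks, 281 overlapped an E9.5 peak by at least 1 bp (27.9%, interval 25.2% to 30.8%), and 282 of the E9.5 peaks overlapped an E8.5 peak (22.8%, 20.5% to 25.2%), in 289 pairs. Random positions on the same chromosome gave a mean of 0.0550% and 0.0491% over 1000 placements. When each peak was moved only within its own 1 Mb window, the mean was 1.88% and 1.53%, and the highest placements reached 3.38% and 2.58%. Peaks with a q of at most 0.05 were mostly found in both lists, 104 of 129 at E8.5 (80.6%, 72.7% to 87.0%) and 107 of 159 at E9.5 (67.3%, 59.4% to 74.5%). They included 17 peaks per library with pileups of at least 1000, of which 16 were shared. The folds of those 17 were at most 1.78 at E8.5 and 1.79 at E9.5. Among peaks with a larger q the shares were 20.2% and 16.2%. When both lists were limited to a q of at most 0.001, the shares were 60.5% and 50%. Because both lists were called against the same input, part of the excess over random placement may come from that input. Among peaks whose background was the genome-wide minimum, where the local input did not enter, 11.2% of the E8.5 peaks and 6.29% of the E9.5 peaks overlapped the other list.

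**Figure D1:**
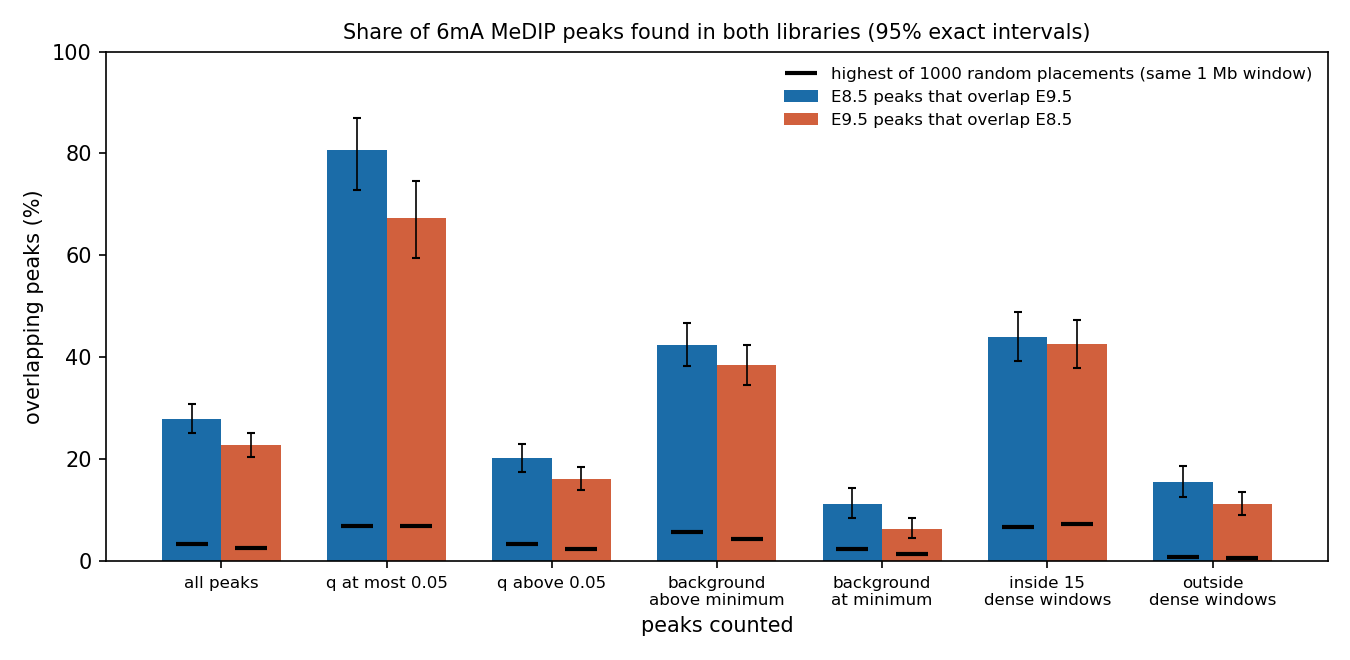
Bars give the percentage of E8.5 peaks that overlap an E9.5 peak and of E9.5 peaks that overlap an E8.5 peak, for all peaks and for subsets by q-value, by background and by position, with exact 95% intervals, and black marks give the highest share in 1000 random placements within the same 1 Mb windows. Peaks with a q of at most 0.05 reach 80.6% and 67.3%, against 20.2% and 16.2% for the remaining peaks.

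The most enriched region shared by both libraries held no annotated protein-coding or long non-coding gene. It lay on chromosome 9 (68150548 to 68151287 at E8.5), with a pileup of 26 and a fold of 6.66 at E8.5 and a pileup of 30 and a fold of 7.49 at E9.5. The next lay inside Sp100, which encodes a protein of PML nuclear bodies, on chromosome 1 (85651025 to 85651796), with folds of 5.95 and 5.47. A further pair on the same chromosome lay within 2 kb of Gm7592 (85556543 to 85556946), with folds of 4.74 and 5.13. Gm2977 on chromosome 14 (3545597 to 3546170) carried folds of 4.52 and 5.80. The long non-coding genes 3632454L22Rik on chromosome X (135053694 to 135054430) and Gm47990 on chromosome 13 (38338323 to 38338654) carried folds of 4.44 and 6.28, and of 4.44 and 4.35. The other pairs among the 8 highest ranked had no protein-coding or long non-coding gene within 2 kb. They lay on chromosome 14 at 43335866 to 43337588, with folds of 4.52 and 4.77, and on chromosome X at 32093143 to 32093470, with folds of 4.20 and 5.07. Folds are listed at E8.5 and then at E9.5, and positions are those of the E8.5 peak. The pileups of these pairs lay between 16 and 30, and the intervals of each pair overlapped.

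Among peaks without a partner at E9.5, the E8.5 peak with the highest fold lay inside the long non-coding gene Gm30613 on chromosome 5 (15604600 to 15605004), with a pileup of 18 (interval 10.7 to 28.4) and a fold of 4.69. Gm15319 on chromosome 8 (20346186 to 20346735) held a peak with a pileup of 22 and a fold of 4.24. A peak inside Actb, the gene of cytoplasmic beta-actin, and within 2 kb of Gm38733 on chromosome 5 (142905339 to 142905693) had a pileup of 16 (9.15 to 26.0), a fold of 4.20 and a q of 0.00394. The same pileup and fold were found at 4 positions with no protein-coding or long non-coding gene within 2 kb. These lay on chromosome 5 at 93907373 and 94902733 and on chromosome X at 32074178 and 32588507. The last of these 8 peaks, on chromosome 3 at 102434524, had a pileup of 15 and a fold of 3.95.

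Among peaks without a partner at E8.5, the E9.5 peak with the highest fold lay inside Arhgef38 on chromosome 3 (133124270 to 133124645), with a pileup of 20 (interval 12.2 to 30.9), a fold of 5.00 and a q of 6.36e-06. A peak within 2 kb of Gm51573 on chromosome 8 (55371916 to 55372279) had the most fragments of the E9.5 peaks named by this ranking, a pileup of 42 (30.3 to 56.8), with a fold of 4.78 and a q of 1.15e-12. Peaks on chromosome 18 at 82162411 and on chromosome 4 at 10136951, with no protein-coding or long non-coding gene within 2 kb, both had a fold of 4.59. The remaining 4 each had a pileup of 17 and a fold of 4.35, and lay on chromosome 1 at 142498778, on chromosome 18 at 3096258, on chromosome 8 at 20006380 and within 2 kb of the long non-coding gene Gm52805 on chromosome 5 at 14917885. Absence from the other list says only that no peak was called there, since the lists hold no values outside peaks.

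Shared peaks were longer, had higher pileups and had a higher median fold than peaks of a single library, but their folds were also more spread, with first quartiles of 2.27 against 2.37 at E8.5 and 2.32 against 2.38 at E9.5. The median fold at E8.5 was 2.80 for 281 shared peaks and 2.50 for 725 others, a difference of 0.306 (two-sided permutation test over peaks, p = 1e-05, the smallest that the permutations can give, adjusted p = 1.2e-05 over 6 tests). At E9.5 the medians were 2.78 for 282 shared peaks and 2.62 for 957 others, a difference of 0.163 (permutation p = 0.0069, adjusted p = 0.0069). The median length of shared peaks was 452 bp at E8.5 and 477.5 bp at E9.5, against 310 and 333 bp for the others, and the median pileup was 17 and 18 against 10 and 10 (permutation p = 1e-05 for each). These tests compare peaks within a library, neighbouring peaks are not independent, and a longer peak has more room to overlap another. With 15 windows rich in peaks left out, a choice made after the data were examined, the differences in fold were 0.121 (permutation p = 0.65) and 0.0408 (permutation p = 0.28).

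Peaks gathered on a few chromosomes and in a few stretches of them. Chromosome X held 177 E8.5 peaks (17.6%, interval 15.3% to 20.1%) and 196 E9.5 peaks (15.8%, 13.8% to 18.0%), against 6.31% of the spans covered by genes and peaks. Chromosome 4 held 12.03% and 10.5% against 5.78%, chromosome 8 held 10.1% and 8.80% against 4.78%, and chromosome 14 held 7.36% and 8.80% against 4.61%. Chromosome 11 held 2.19% and 1.37% against 4.51%, and chromosome Y held 2 peaks and 1 peak. Outside the 15 windows described next, the share on chromosome X was 10.0% at E8.5 and 10.9% at E9.5, that on chromosome 4 was 7.04% and 6.26%, that on chromosome 8 was 5.99% and 5.36%, and that on chromosome 14 was 5.81% and 6.00%. Chromosome 11 held 3.87% and 2.17% of the peaks outside those windows. Among peaks with a q of at most 0.001 the share on chromosome X was 9.21% (3.78% to 18.1%) and 13.3% (7.08% to 22.1%).

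**Figure D2:**
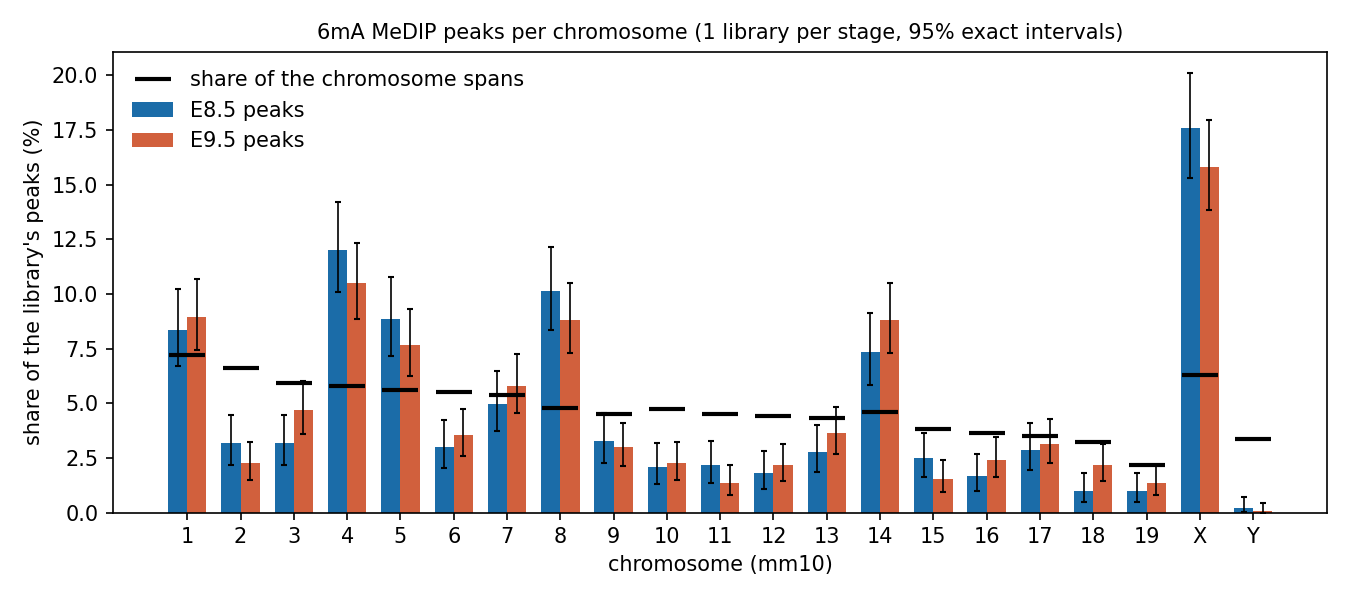
Bars give the percentage of each library's peaks on each chromosome, with exact 95% intervals, and black marks give each chromosome's percentage of the summed chromosome spans. Chromosome X holds 17.6% of the E8.5 peaks and 15.8% of the E9.5 peaks against 6.31% of the spans.

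A set of 15 windows of 1 Mb, those with at least 10 peaks in both libraries and 0.555% of the spans in all, held 438 E8.5 peaks (43.5%, interval 40.4% to 46.7%) and 456 E9.5 peaks (36.8%, 34.1% to 39.6%). The windows were chosen after the data were examined. The most crowded lay between 31 and 32 Mb of chromosome X, among the Btbd35f and Spin2 gene families, with 77 and 65 peaks. A window between 20 and 21 Mb of chromosome 8, which holds predicted genes and the beta-defensin gene Defb33, held 53 and 52 peaks, and a window between 43 and 44 Mb of chromosome 14, which holds predicted genes and the ribonuclease genes Ear1, Ear10 and Ang5, held 41 and 62. A window between 147 and 148 Mb of chromosome 4, in a cluster of Zfp zinc finger genes, held 47 and 42. Between 85 and 86 Mb of chromosome 1, 48 and 50 peaks lay in the part that holds Sp110, Sp140, Sp100 and related predicted genes, and 8 of the 13 protein-coding genes there held an E8.5 peak and 9 an E9.5 peak. Cab39, Itm2c and Gpr55 in the same window held none. The median background of the peaks in this window was 9.87 fragments at E8.5, against a genome-wide minimum of 3.05, while in the window between 31 and 32 Mb of chromosome X it was 3.48. Overlap between the libraries was 44.1% and 42.5% inside the 15 windows and 15.5% and 11.2% outside them.

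**Figure D3:**
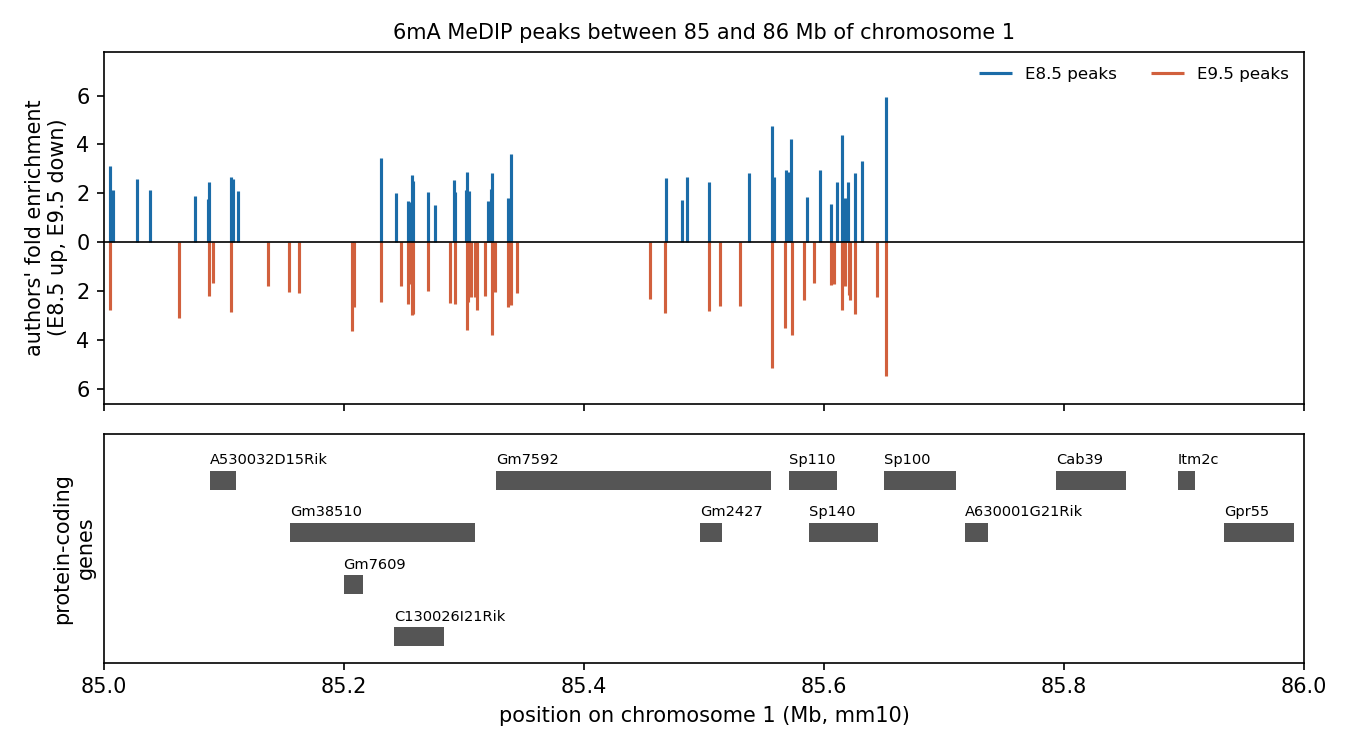
Vertical lines mark peaks between 85 and 86 Mb of chromosome 1 (mm10) with the authors' fold enrichment as their height, E8.5 upwards and E9.5 downwards, and grey bars mark protein-coding gene bodies. The 48 E8.5 and 50 E9.5 peaks lie to the left of A630001G21Rik, and the tallest line of each library lies in Sp100.

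Gene bodies held fewer peaks than random positions did. By summit, 329 E8.5 peaks (32.7%, interval 29.8% to 35.7%) and 397 E9.5 peaks (32.0%, 29.4% to 34.7%) lay inside a protein-coding or long non-coding gene and more than 1 kb from any gene end. The mean over 1000 random placements on the same chromosomes was 41.3% and 41.2%. Intergenic peaks made up 63.3% (60.3% to 66.3%) and 64.7% (62.0% to 67.4%), above the highest random values of 60.1% and 58.8%. Among peaks with a q of at most 0.001 the intergenic shares were 57.9% (46.0% to 69.1%) and 56.7% (45.8% to 67.1%), intervals that hold the random mean of 54.3%, so the excess was not detectable in those peaks. Positions within 1 kb of a gene end held 3.98% and 3.23%, and 95% of the random placements lay between 3.18% and 5.77% at E8.5 and between 3.39% and 5.73% at E9.5. Promoters, exons and introns were not told apart, because strand and exon positions were not used here.

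No peak lay at the listed genes of neural tube closure, folate metabolism or chromatin at either stage when genes were extended by 2 kb. None of the 84 neural tube closure genes, the 38 folate metabolism genes, the 23 genes of 6mA and cytosine methylation enzymes or the 49 genes of H3K9 methylation and heterochromatin had a peak in the gene body or within 2 kb of it in either library. Nor did any of the 39 Hox genes, 20 neural crest markers, 27 mesoderm and somite markers, 19 surface ectoderm and endoderm markers or 28 pluripotency and germline genes. These lists are short, and random lists of genes of the same lengths gave a mean of 1.11 and 1.41 genes for the neural tube closure list, so a count of 0 is not rare. With genes extended by 10 kb, 1 neural tube closure gene, 1 neural crest marker and 1 surface ectoderm or endoderm marker had an E9.5 peak, and 1 gene of H3K9 methylation and heterochromatin had an E8.5 peak. Over all 15 lists, 9 of 670 genes had an E8.5 peak and 17 an E9.5 peak, against random means of 12.1 (95% of lists between 6 and 19) and 17.5 (between 10 and 25). At a q of at most 0.001, 2 of these genes were left in each library. Random lists not matched on gene length turned the ratio to random lists from 0.743 to 1.40 at E8.5 and from 0.973 to 2.13 at E9.5.

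Smo, which encodes the membrane protein Smoothened that transduces hedgehog signals, was the signalling gene with a peak in both libraries. Its peak on chromosome 6 (29748015 to 29748621 at E8.5) lay inside the gene body, with a pileup of 91 and a fold of 2.72 at E8.5 (q = 6.11e-12) and a pileup of 87 and a fold of 3.21 at E9.5 (q = 8.87e-16). The background there was 32.8 and 26.4 fragments, well above the genome-wide minimum. Among the 71 genes of Wnt, Shh, BMP, FGF and retinoid signalling, 2 had a peak in each library, the others being Fgf13 at E8.5 (fold 2.71) and Fgf14 at E9.5 (fold 2.41). Dlgap2, which encodes a postsynaptic scaffold protein, was the synapse gene with a peak in both libraries. That peak lay inside the gene on chromosome 8 (14306846 to 14307357 at E8.5), with a pileup of 58 and a fold of 2.52 at E8.5 (q = 2.06e-05) and a pileup of 62 and a fold of 2.61 at E9.5 (q = 1.22e-06), over a background of 22.4 and 23.2 fragments. The input was thus raised at both Smo and Dlgap2. Whether extra copies of the sequence raised pull-down and input alike there was not tested.

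More members of the synapse and ion channel list had a peak at E9.5 than at E8.5, 10 of 79 against 4 of 79, a difference that was not tested. The E9.5 members include Fhit (fold 2.41), which encodes neither a synaptic protein nor an ion channel. The E9.5 list was also longer, with 1239 peaks against 1006. At a q of at most 0.001, 1 of these genes was left in each library. Random lists of the same gene lengths gave a mean of 3.56 at E8.5 and 5.85 at E9.5, and 6.09% of them reached 10 or more at E9.5. The members with the highest folds were Grid1 (3.14 at E9.5) and Grm7 (2.96 at E8.5), which encode glutamate receptors, Dlgap1 and Tenm4 (2.66 each at E9.5), Dlgap2, and Dmd (2.47 at E8.5), the dystrophin gene. Of the 78 axon guidance and cell adhesion genes, Sema5a, Negr1 and Pcdh15 had a peak at E8.5 (folds 2.71, 2.47 and 2.47) and Cntnap2 and Ntng1 at E9.5 (folds 3.14 and 2.90), against random means of 3.09 and 5.03. At E9.5 alone, single peaks lay in Tcf7l2 (fold 2.62), a Wnt effector among the 61 neural progenitor and patterning factors, in Tek (2.41), an endothelial receptor among the 28 blood and endothelial markers, and in Kcnq1 (2.62), among the 29 imprinted genes. Each gene named here with a fold, other than Dlgap2 and Smo, rested on peaks with a q of 1 and pileups of 12 or fewer.

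Across all 21883 protein-coding genes, 211 had a peak at E8.5 and 262 at E9.5, and 71 had one in both. Independent lists would share 6.65 when gene length is taken into account and 2.53 when it is not, and outside the 15 windows 37 genes had a peak in both, against 5.38 with gene length taken into account. In each library 50 genes held a peak that overlapped one of the other library. Zfp zinc finger genes, many of which encode transcriptional repressors, had a peak in 14 of 397 members in each library, with 11 in both, against random means of 2.99 and 3.72. Outside the 15 windows 2 and 3 of them had a peak, and at a q of at most 0.001 the counts were 1 and 2. Their highest folds were at Zfp980 (4.83 at E9.5, q = 2.94e-05), Zfp985 (4.76 at E8.5, q = 4.93e-05), Zfp984 (4.11 at E9.5), Zfp993 (3.79 at E9.5), and Zfp978 and Zfp988, which share a peak (3.73 at E8.5), all on chromosome 4. Mup, Skint, Speer and Prame family genes had a peak in 11 of 93 at E8.5 and 9 of 93 at E9.5, with 2 in both, against random means of 0.720 and 0.807. Outside the 15 windows 7 and 6 of them had a peak, at a q of at most 0.001 none had one, and each member named next had a q of at least 0.0864. The highest folds there were at Pramel43 and Pramel44, which share a peak (3.62 at E9.5), Mup5 (3.14 at E9.5), Mup-ps16 (2.96 at E8.5), Skint8 (2.90 at E9.5) and Pramel34 (2.82 at E9.5). The random lists were not matched on position, while some members of these families are neighbours that share a peak. Counts of such genes are therefore not counts of independent regions.

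Vomeronasal receptor genes had a peak in 6 of 355 at E8.5 and 5 of 355 at E9.5, with 0 in both, against random means of 1.59 and 1.77. With no extension of the gene the counts were 5 and 2, with an extension of 10 kb they were 10 and 10, at a q of at most 0.001 they were 0 and 0, and the peaks named next had a q of 1 except that at Vmn2r114 (q = 0.101). The highest folds were at Vmn2r114 (3.40 at E8.5), Vmn1r160 (2.96 at E8.5), Vmn1r157 (2.86 at E9.5), Vmn1r3 (2.71 at E8.5), Vmn1r18 (2.62 at E9.5) and Vmn1r238 (2.47 at E8.5). None of 1110 olfactory receptor genes had a peak, against random means of 2.43 and 2.78, and 2 and 3 had one with genes extended by 10 kb. Of 57 clustered protocadherin genes, 12 were counted at E9.5 and 0 at E8.5, but all 12 were Pcdha genes whose annotated bodies overlap 1 peak on chromosome 18 (37044158 to 37044429, pileup 9, fold 2.00, q of 1). Members of these families resemble one another in sequence, so fragments from one copy can be placed on another.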

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

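Tests that left out the 15 peak-rich windows, used a q of at most 0.05, placed peaks within 1 Mb windows or counted each window once were chosen after the results were seen. Of the 82 alternative values of the main results, 35 stayed within the counting interval, within 1.5 times a count or on the same side of the test, 45 moved and 2 lost their call. Values below are for E8.5 and then E9.5. At a q of at most 0.001, peak counts were 76 and 90, overlap 60.5% and 50%, the chromosome X share 9.21% and 13.3%, the intergenic share 57.9% and 56.7%, and list genes 2 and 2. With the upper 50% of folds the counts were 514 and 620, overlap 23.9% and 19.7%, chromosome X 23.2% and 20%, intergenic 66.5% at E8.5, and list genes 4 and 6. Without the 15 windows the counts were 568 and 783, overlap 15.5% and 11.2%, and chromosome X 10.0% and 10.9%. The difference in fold between shared and other peaks then fell to 0.121 (permutation p = 0.65) and 0.0408 (permutation p = 0.28). At a q of at most 0.05 the counts were 129 and 159, and their overlap with all peaks of the other library, not only those at that q, was 80.6% and 67.3%, and 81.3% and 62.7% outside the 15 windows. Counts fell by construction under each of these filters, and the cause of the other changes was not tested. Overlap was 19.9% and 16.1% at 50% reciprocal overlap, 34.2% and 27.4% within 1 kb, and 25.7% at E9.5 with equal numbers of peaks. The ratio of overlap to random placement was 508 and 464 on the same chromosome and 14.9 and 14.9 within windows. Each window counted once gave 9.11% and 10.2% on chromosome X. Intergenic shares were 59.6% and 60.9% with 3 kb around gene ends and 69.9% and 71.8% with protein-coding genes only, which widen and narrow what counts as a gene. Random lists not matched on length gave a ratio of 2.13 at E9.5, where 3.14% of the longest 25% of genes and 0.402% of the shortest 25% had a peak. Leaving out chromosome Y, the 1% of peaks with the highest pileup, or merging peaks within 1 kb moved none of the main values they were run on beyond those bounds.

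Among counts for single lists, 198 of the alternative values stayed within 1.5 times and 42 did not. Alternatives for base content, and the promoter width as such, were not run, because sequence and strand were not used here. Depth limits the peaks outside the few strongest, since a pileup of 11 has a wide counting interval.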

Other observations

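The test of peaks by q-value was chosen after the result was seen, as were the windows in which the other tests were run, while the outcomes those other tests look for were written down first.

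Of 1327 protein-coding genes with Gm symbols, which mark predicted genes, 32 had a peak at E8.5 and 43 at E9.5. Random lists matched on gene length, but not on position, gave means of 7.63 and 8.51, with 95% between 3 and 13 and between 4 and 14. Outside the 15 windows the counts were 18 and 25, against means of 5.15 and 6.52 (95% of lists between 1 and 10 and between 2 and 12). This group was chosen after the data were examined. Pramel genes, relatives of a germline and tumour antigen family, held a peak in 7 of 46 members at E8.5 and 5 at E9.5, with 1 in both. Inside the 15 windows lay the peaks of Pramel38, Pramel39, Pramel40 and Pramel42 at E8.5, and of Pramel43, Pramel44 and Pramel48 at E9.5. Pramel39 and Pramel40 share a peak, as do Pramel43 and Pramel44, and each Pramel peak had a q of at least 0.0864. Among the 10 windows not described above, with between 11 and 26 E8.5 peaks, those on chromosome 17 between 13 and 14 Mb, which holds the t-complex genes Smok2a, Smok2b and Tcp10b, and on chromosome 8 between 19 and 20 Mb, which holds beta-defensin genes, carried 15 E8.5 peaks each and are named for their genes. A further one, between 3 and 4 Mb of chromosome 9, held 15 E8.5 and 13 E9.5 peaks. Its median fold was 1.56 and 1.57, over a median background of 3640 and 3902 fragments. In each library 12 of its peaks were shared and 13 had a q of at most 0.05.

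The highest stacks of fragments were not the most enriched regions. In each library 17 peaks had a pileup of at least 1000, of which 16 were shared, at 98.7 Mb of chromosome 2, at 3.00 and 35.3 Mb of chromosome 9 and at 19.4 Mb of chromosome 14. Their pileups reached 106596 at E8.5 and 109823 at E9.5, but their folds lay between 1.10 and 1.78 and between 1.08 and 1.79. All of them were among the peaks with a q of at most 0.05, and at E8.5 all 17 also had a q of at most 0.001.

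Peaks of the libraries overlapped far more often than randomly placed peaks. Crowding of peaks at the scale of 1 Mb was not the whole cause. Of E8.5 and E9.5 peaks 27.9% and 22.8% overlapped, against at most 3.38% and 2.58% in 1000 placements within the same 1 Mb windows. Those placements spread peaks evenly over each window, so crowding at a finer scale was not tested. The shared input did not set the background of peaks with the minimum background, and 11.2% and 6.29% of those overlapped. Such placements gave at most 2.36% and 1.49% for them, so the outcome written down for the input as the cause was not found. The placements also covered positions where the input was higher, and partners could have any background. The part of the input was therefore not isolated. Recurrent 6mA, recurrent capture of certain sequences by the antibody, and recurrent placement of fragments from repeated sequence may each account for the overlap, and none of these was tested.

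Peaks gathered in 15 windows. A candidate explanation is extra copies of the sequence that raise pull-down and input alike: only 18.9% (interval 15.4% to 22.9%) of E8.5 and 18.0% (14.6% to 21.8%) of E9.5 peaks in these windows had the minimum background, against 67.4% and 66.7% elsewhere. This was the outcome that extra copies predict, but not in every window: on chromosome X between 32 and 33 Mb, 14 of 20 E8.5 and 16 of 22 E9.5 peaks had the minimum background, between 33 and 34 Mb 12 of 23 and 12 of 24 had it, and on chromosome 5 between 95 and 96 Mb 8 of 16 E9.5 peaks had it. The minimum of 3.05 and 3.14 fragments lies above the mean coverage of 1.46 and 1.54. A background at the minimum may therefore hide a modest rise in the input, and cannot exclude extra copies in these windows. The peaks still had folds above the input, and the test does not say why. H3K9me3 marks, named in the series title, were not analysed here, so no biological explanation was tested.

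Most peaks of each library had no partner in the other. Sampling near the calling threshold is a candidate explanation, since 80.6% (72.7% to 87.0%) of E8.5 and 67.3% (59.4% to 74.5%) of E9.5 peaks with a q of at most 0.05 overlapped, against 20.2% and 16.2% of the others. Limiting both lists, which also removes partners, gave 60.5% and 50% at a q of at most 0.001. With the upper 50% of folds it gave 23.9% and 19.7%, against 27.9% and 22.8% for all peaks. Median folds were higher for shared peaks, 2.80 against 2.50 at E8.5 and 2.78 against 2.62 at E9.5. Outside the 15 windows the permutation test detected no such difference in either library. The peaks with a q of at most 0.05 included 17 per library with pileups of at least 1000, of which 16 were shared. Such high peaks made up 16 of the 104 shared E8.5 and 16 of the 107 shared E9.5 peaks at that q. Most of that overlap therefore came from other peaks. The 15 windows held 81 and 92 of the peaks with a q of at most 0.05, but outside them the shares were 81.3% (67.4% to 91.1%) and 62.7% (50.01% to 74.2%), against 9.42% and 6.42%. Another 25 E8.5 and 52 E9.5 peaks with a q of at most 0.05 had no partner, and whether sampling accounts for these was not tested: at Actb the pileup of 16 has an interval that starts at 9.15, close to the lowest called pileup of 8, and at Gm51573 the pileup of 42 has one that starts at 30.3. A difference between the stages also stays open and was not tested, since each stage had 1 library.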
